A study of Gallus gallus with 28 samples.

How the data were processed

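RNA was extracted with Trizol and sequenced from 28 libraries of chicken skin, per the labels' protocols: E9 dermis and adult feather follicles of White Leghorn chickens from 5 regions, E13 comb skin after injection at E4 of a retrovirus with HoxC8 and its control, and crest and short cranial feather mesenchyme of juvenile Polish chickens. The labels name TruSeq v2 kits for E9 dermis, SMART-Seq v4 for the Polish mesenchyme and NEBNext Ultra for the others. Every group holds 2 libraries. The control combs are labelled as having no treatment, and the series text calls the control an empty vector.

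Per the submitters' processing notes, STAR and Partek were used with the builds GRCg6a and galGal6, with no versions or roles given. The authors deposited, in 4 tables, one estimated count per gene and library; per the file headers the genes are Ensembl models with GRCg6a coordinates. Of the values of a library 12.9% to 28.8% were not whole numbers, and whether reads shared by genes were split, the strand setting and any filter are not given in the sources used here. The authors also deposited TPM (transcripts scaled by length to a total of 1000000) for the same genes. A check of these values showed that 100.0% lay within 1 percent of a model that adds 1 to each count and divides by the whole span of the gene, introns included, so the deposited TPM favours genes with short introns and differs from a TPM over exons. An annotation file was deposited as well, whose start and end coordinates (unit other) were, per the file headers, moved or split around an inserted sequence on chromosome 33. Of its genes on that chromosome 13 were shifted, while 17504 of the 17517 genes of the Polish table start at the same position. Chromatin data of the study were not analysed here.

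The tables list 19005 genes (E9), 16745 (adult), 17638 (comb) and 17517 (Polish), of which 6684, 4885, 5778 and 5523 have no gene name and are counted but not named. A few genes that were tested are not reported here. Library totals ran from 7341134 counts in a comb control to 47819192 in a cranial feather library. A count of 0 in one library allows up to 3 counts, which is 0.409 CPM in the shallowest library and 0.0627 CPM in the deepest. Replicates were compared first: the correlation of log2 CPM across genes was 0.961 or more in each pair except the cranial feather mesenchyme (0.883), and no pair agreed within sampling noise, so none was treated as 1 library. No column lacked a sample.

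Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr on the groups, robust dispersions, glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment over the genes tested in each comparison and a threshold of 0.05. Each table was fitted on its own with all its groups, and levels are not compared across tables. Back is the mean of the anterior and posterior dorsal coefficients, so a fold against back is against a geometric mean, while the CPM of back is the arithmetic mean of 4 libraries. Tests of all regions used 4 coefficients. The stage test fitted the E9 and adult tables together on the genes listed in both, with a term for each group, and tested the difference of the scalp and tail contrasts; that difference also holds any effect of kit and tissue. Overlaps of calls used a one-sided Fisher's exact test per direction. Region markers passed the test of all regions and exceeded each other region with an unadjusted p under 0.05 and a log2 fold of at least 1.

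A fold against a group with 0 counts is a lower bound against 3 counts over the group. Where the lower group held 1 to 3 counts, the ratio of totals scaled by effective library size is given with its exact 95% counting interval. No fold is given where both groups are at or under the floor. Reads of near-identical genes (feather keratins such as F-KER, and genes of the epidermal differentiation complex such as EDQM3 and EDMPN2) could be split between copies, so their values are uncertain.

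The comparisons, the lists and the rule for named genes were fixed before the data were examined. The named genes are all HOX genes; the 8 largest positive and 8 largest negative changes per comparison among named genes with at least 5 CPM in the higher group and no overlap between groups; up to 4 members of each list by smallest p (2 where none pass); up to 5 markers per region; genes on chromosome W; and, for the stage test, HOX genes and the 8 genes with the smallest p. The 30 lists hold the HOXA, HOXB, HOXC and HOXD clusters; cranial mesenchyme and trunk and limb transcription factors; feather bud and placode genes; feather and epidermal differentiation; markers of dermal fibroblasts, keratinocytes, skeletal muscle, smooth muscle and pericytes, neural and Schwann cells, melanocytes, endothelium, erythroid cells, leukocytes, cartilage and bone, and adipocytes; WNT, BMP and TGF-beta, hedgehog, FGF, Notch and retinoic acid pathways; matrix remodelling, proliferation, immediate early and stress, and interferon genes; and the mitochondrial genome. Lists were tested with camera of limma 3.58.1 (preset correlation, log2 CPM with a prior count of 2), again with an estimated correlation, and with fry, each with Benjamini-Hochberg adjustment over the 30 lists of a comparison. Camera with an estimated correlation rests on the residual degrees of freedom, 5 in each regional fit and 2 in the HoxC8 and crest fits. At 2 it had little power.

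Alternatives were DESeq2 1.42.0, DESeq2's size factors in edgeR, no filter and a stricter filter of 1 CPM, limma-trend on log2 of the deposited TPM plus 1, an added limit of a log2 fold of at least 1, genes on Z and W left out, the replicate number as a block, each dorsal region alone as back, fits of the compared regions alone, and each library left out in turn. The limma fit of the deposited TPM applied no further scaling between libraries. Covariates for the keratinocyte level and the W chromosome level were added after the data were seen. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9.

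The fits were tested on simulated counts drawn from the means and library sizes of each comparison, in a single run each. Changed genes were drawn only from genes above a limit of mean counts, so recovery of genes with few counts was not measured. They were also few beside the genes called in most comparisons, so the false rates below need not carry over to those calls. Of 100 genes changed 2-fold the test recovered 62 in E9 scalp against back, 62 in E9 back against tail, 52 in E9 scalp against tail, 81, 89 and 79 in the adult comparisons in the same order, 66 in the HoxC8 comparison, 0 in the crest comparison and 45 in the stage test. Of 100 changed 4-fold it recovered 92, 84, 80, 98, 100, 96, 96, 0 and 85. False genes made up 7.23, 6.41, 8.33, 7.25, 7.35, 7.41, 8.48, 0 and 3.70 percent of calls in the same order, so 7 of the 9 rates lay above the nominal 5 percent, as did those of the tests of all regions (10.3 percent at E9 and 9.59 percent in adults). The test of the crest comparison made no call on the simulated data at the spread of those libraries.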

Results

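Transcripts were measured by RNA sequencing in 28 chicken skin libraries that form 14 groups with n = 2 each. White Leghorn chickens gave dermis at embryonic day 9 (E9) and adult feather follicles, each from 5 regions along the body axis: scalp, neck, anterior dorsal skin, posterior dorsal skin and tail. E13 comb skin gave a HoxC8 group, whose scalp was injected at E4 with RCAS, a replication-competent avian retrovirus that carried HoxC8, and a control group. Juvenile Polish chickens, whose genotype label names a short duplication, gave mesenchyme of the long crest feathers and of the short cranial feathers. Total counts were 16999915 to 23141349 per E9 library, 15224640 to 18624947 per adult library, 8060972 and 7341134 in the comb controls, 8252142 and 10040210 in the HoxC8 combs, 32904002 and 31087248 in the crest and 47819192 and 41853631 in the cranial feather mesenchyme. Levels are CPM (counts scaled to a library total of 1000000) with TMM factors, given as mean ± SD. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples. Intervals and floors cover counting error only.

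The 7 HOXC genes of the tables lie on chromosome 33 of GRCg6a, on the plus strand: HOXC13 at 7539365 to 7542378, HOXC12 at 7552387 to 7554125, HOXC10 at 7585953 to 7590530, HOXC9 at 7601322 to 7604178, HOXC8 at 7605746 to 7616596, HOXC6 at 7622308 to 7637089 and HOXC4 at 7661545 to 7663344. Exon 1 of HOXC10 spans 7585953 to 7586778, and its 5′ UTR ends at 7585991. An annotation deposited with the series carries a short insertion in the intron of HOXC10 and splits the gene there, so that its first part ends at 7587782 and its second part begins at 7587978. In that modified annotation exon 2 spans 7589910 to 7590725 and its 3′ UTR starts at 7590188. The count tables use the unmodified coordinates. HOXA lies on chromosome 2 (32577089 to 32682168), HOXB on chromosome 27 (6151929 to 6290582) and HOXD on chromosome 7 (16262309 to 16327333).

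**Figure D1:**
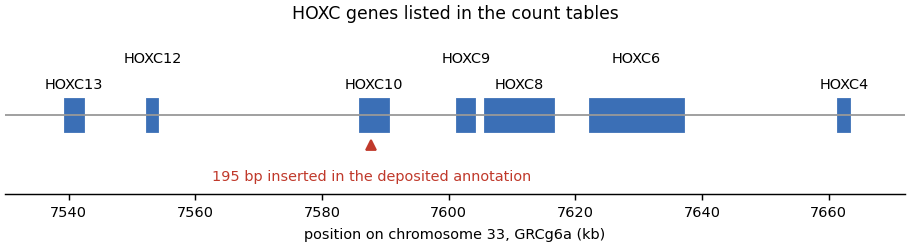
The 7 HOXC genes on chromosome 33 of GRCg6a, drawn to scale with position in kb on the horizontal axis. Boxes are genes, and the triangle marks position 7587782, after which bases are inserted in the deposited annotation, inside the intron of HOXC10.

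The first question was how HOX genes, which encode transcription factors of positional identity, are expressed along the axis. In E9 dermis HOXC8 averaged 58.5 ± 3.33 CPM (SD, n = 2) in anterior dorsal, 30.5 ± 6.03 CPM in posterior dorsal and 5.81 ± 0.494 CPM in tail skin, against 0.0750 CPM in scalp. HOXC10 stood at 0.0499 CPM in scalp, 104 ± 70.9 CPM in anterior dorsal (3234 and 1267 counts in replicates 1 and 2), 274 ± 15.0 CPM in posterior dorsal and 148 ± 1.06 CPM in tail skin. HOXC12 and HOXC13 reached 104 ± 6.50 and 52.8 ± 1.28 CPM in tail. HOXC4 peaked at 4.22 ± 3.88 CPM in anterior dorsal and 2.36 ± 0.634 CPM in neck skin. Of 36 HOX genes listed at E9, 0 had their highest mean in scalp, 9 in neck, 10 in anterior dorsal, 8 in posterior dorsal and 9 in tail. All 33 that were tested differed between regions, by edgeR's quasi-likelihood test over the 5 regions.

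In adult follicles all HOXC genes had 0 counts in both scalp libraries. HOXC10 averaged 84.8 ± 6.33 CPM in posterior dorsal and 49.1 ± 2.79 CPM in tail follicles, but only 0 and 4 counts in the anterior dorsal libraries. HOXC8 averaged 14.4 ± 0.464 CPM in posterior dorsal and 3.52 ± 3.61 CPM in anterior dorsal follicles, where the libraries held 16 and 95 counts. HOXC12 averaged 31.9 ± 0.583 CPM in tail and had 0 counts elsewhere, and HOXC13 reached 22.4 ± 1.43 CPM in tail. HOXC4 and HOXC6 were highest in anterior dorsal follicles, at 6.11 and 3.83 CPM. Of 34 HOX genes listed, 1 was highest in scalp, 5 in neck, 10 in anterior dorsal, 7 in posterior dorsal and 11 in tail follicles, and all 31 tested genes differed between regions. With the deposited TPM those numbers became 0, 3, 7, 11 and 13. The gene highest in scalp by CPM had too few counts to be tested.

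**Figure D2:**
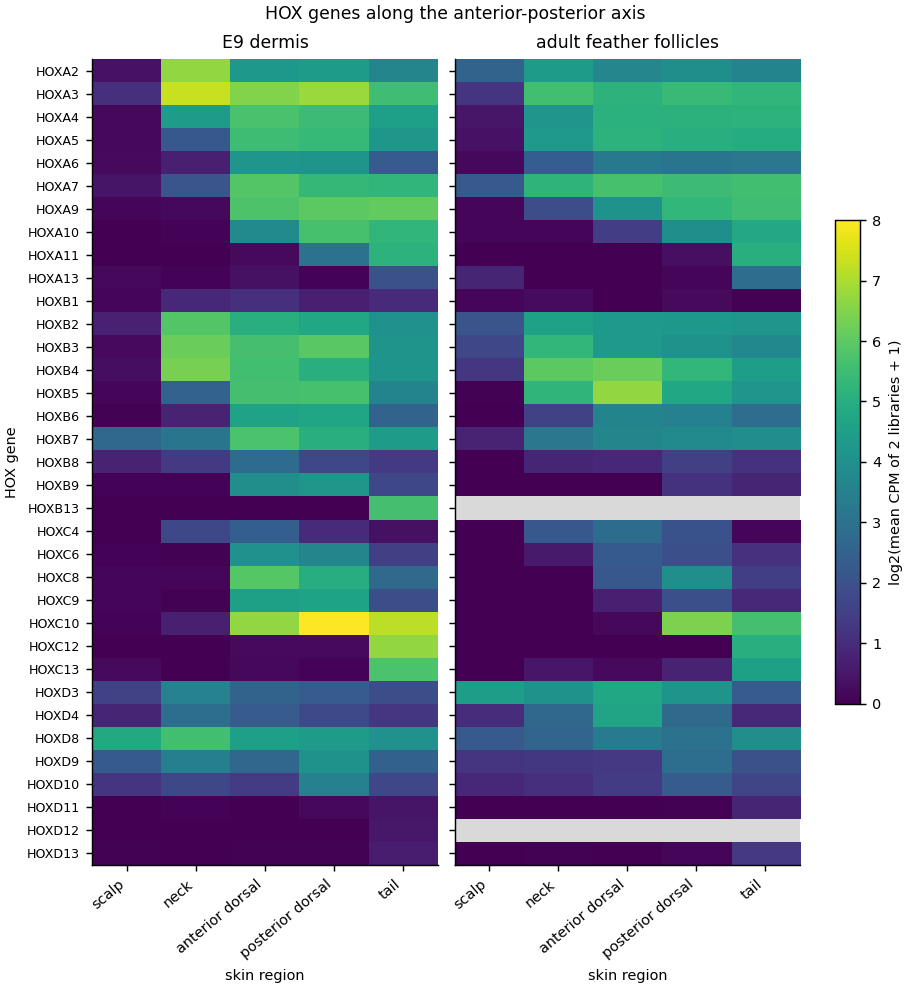
Expression of HOX genes, one per line, in 5 skin regions of E9 dermis (left) and adult feather follicles (right). Colour gives log2 of the mean CPM of 2 libraries plus 1, and grey marks a gene that a table does not list; scalp lacks the HOXC signal of dorsal and tail skin, where HOXC10 averaged 274 CPM at E9 in posterior dorsal dermis.

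The E9 scalp and back comparison asked which genes set head skin apart from dorsal skin, with back as the mean of the anterior and posterior dorsal coefficients. HOXC8 was 607-fold higher in back (95% counting interval 208 to 2946) and HOXC10 3628-fold (1004 to 29960). HOXC6 and HOXC9 were higher in back 275-fold (75.9 to 2272) and 305-fold (104 to 1479), and HOXC4, at 0 counts in scalp, was at least 37.4-fold higher. HOXA5 (42.8 ± 4.33 against 0.125 ± 0.0362 CPM) and HOXB5 (49.3 ± 1.56 against 0.10 ± 0.0713 CPM) showed the same order. Several other transcription factor genes were higher in scalp: GSC averaged 135 ± 10.6 CPM in scalp and 0.851 ± 0.715 in back (204-fold), PAX9 64.3 ± 7.83 and 0.40 ± 0.267 CPM (188-fold), and ALX1 was 2580-fold higher in scalp (714 to 21320). EN1, a homeobox gene of several embryonic territories, was 15.1-fold and ASIP, which encodes the agouti signalling protein of pigment patterning, 86.5-fold higher in scalp.

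By list, 10 of 11 HOXA genes, 9 of 10 HOXB genes and 6 of 7 HOXC genes were lower in scalp, and as many when adjusted over the list alone. Those 6 include HOXC12, whose mean was at most 0.155 CPM in any region outside tail, near the floor. Camera called HOXA and HOXB (both adjusted p = 4.62e-10, and adjusted p = 0.0143 with an estimated correlation) and HOXC (adjusted p = 7.75e-05, and adjusted p = 0.0581 with an estimated correlation), while HOXD, with 1 gene higher and 4 lower of 5, was not called (adjusted p = 0.142). Of 19 cranial mesenchyme transcription factors 7 were higher in scalp, SIX2 among them (10.8-fold), and 1 was lower (ZIC1, 7.79-fold higher in back), or 9 and 2 adjusted over the list alone (camera adjusted p = 0.0138, and adjusted p = 0.180 with an estimated correlation). Of 21 trunk and limb positional factors 10 were higher, including EN1 and PAX9, and 3 lower, including MEIS2 at 2.60-fold, with the same counts adjusted over the list alone (adjusted p = 0.0274, and adjusted p = 0.612 with an estimated correlation).

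At E9, of 19 feather bud and placode genes 9 were lower in scalp and 2 higher (12 and 3 adjusted over the list alone), with PRDM1 6.01-fold, SOX18 5.20-fold and TNC, an extracellular matrix glycoprotein, 5.19-fold higher in back (camera adjusted p = 0.0138, and adjusted p = 0.437 with an estimated correlation). Keratinocyte genes had a median log2 of -3.19 in the same comparison, though only TP63 passed, and summed to 1789 CPM in anterior dorsal replicate 2; with their level as a covariate PRDM1, SOX18 and TNC still passed, at log2 folds of -2.63, -2.48 and -2.22. Of 11 hedgehog pathway genes 6 were lower and none higher (6 lower and 1 higher adjusted over the list alone): the hedgehog-binding HHIP averaged 5.42 ± 1.77 CPM in scalp and 90.0 ± 20.8 in back, and GLI1 was 2.41-fold higher in back (adjusted p = 0.00703, and adjusted p = 0.437 with an estimated correlation). Smooth muscle and pericyte genes were lower for 6 of 10, on either adjustment, led by MYH11 (33.1-fold higher in back, 199 ± 107 CPM) and its regulator MYOCD (23.3-fold), with adjusted p = 0.00178, and adjusted p = 0.437 with an estimated correlation. That list summed to 430 and 411 CPM in the scalp libraries and 1250 and 877 CPM in the posterior dorsal ones. Of 18 proliferation genes 5 were higher in scalp and 1 lower, or 6 and 1 adjusted over the list alone (adjusted p = 0.0468, and adjusted p = 0.845 with an estimated correlation).

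WNT pathway genes went both ways in the E9 scalp, 6 higher and 14 lower of 38, or 7 and 15 adjusted over the list alone. RSPO3, a secreted WNT enhancer, was 9.30-fold higher in scalp, and its receptor gene LGR5 15.6-fold higher in back, at 252 ± 54.8 CPM. Of 29 BMP and TGF-beta genes 7 were higher and 10 lower (7 and 11 adjusted over the list alone), with BMP2 3.14-fold higher in scalp. Of 14 retinoic acid pathway genes 3 were higher and 4 lower (4 and 4 adjusted over the list alone): STRA6, a retinol transporter gene, was 29.4-fold higher in back and DHRS3 2.71-fold higher in scalp. FGF pathway genes numbered 6 higher and 9 lower of 24, Notch genes 2 and 5 of 16, matrix remodelling genes 5 and 4 of 21, with HAPLN1 86.3-fold higher in back, and cartilage and bone genes 3 and 2 of 13. Adjusted over the list alone these were 6 and 10, 4 and 7, 5 and 4, and 3 and 2. Camera called none of these lists.

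In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 4943 of 15330 genes between E9 scalp and back, 2251 higher and 2692 lower in scalp. With the deposited TPM and limma the split was 769 and 1787, and the median gene lay at -0.12 on the log2 scale, against -0.05 with TMM. Without scalp replicate 1 the count was 2693, and without scalp replicate 2 it was 2424. W chromosome genes gave 44.9 and 2426 CPM, here without TMM factors, in the scalp replicates, so the libraries of this group differed in that respect.

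The E9 back and tail comparison asked what distinguishes dorsal from tail skin. The middle HOXC genes were higher in back: HOXC6 7.25-fold (13.6 ± 2.22 against 1.85 ± 0.0824 CPM), HOXC8 7.26-fold and HOXC9 8.32-fold. The posterior genes were higher in tail: HOXC12 688-fold, HOXC13 588-fold, HOXB13 4059-fold (728 to 160400) and HOXA11 35.5-fold. The HOXA11 value rests on near-zero anterior dorsal counts, with a log2 fold of -5.15 for back, -7.95 for anterior dorsal alone and -2.35 for posterior dorsal alone. HOXC10 averaged 189 ± 107 CPM in back and 148 ± 1.06 CPM in tail and did not pass. EN1 was 4.05-fold and RSPO3 12.9-fold higher in tail, as was MAB21L2, 74.4-fold. The hedgehog pathway had 7 of 11 genes higher in back and none lower, on either adjustment, with HHIP 6.54-fold and GLI3 3.76-fold, and matrix remodelling genes had 10 higher and 3 lower of 21 (10 and 4 adjusted over the list alone). PDGFRA and POSTN, genes of dermal fibroblasts, were 3.39-fold and 3.43-fold higher in back, among 5 higher and 0 lower of 15 fibroblast genes (4 and 0 adjusted over the list alone). Endothelial genes were higher in back for 4 of 9 (5 adjusted over the list alone), and WNT pathway genes for 11, with 9 lower, of 38 on either adjustment, among them AXIN2 (2.19-fold) and NKD1 (2.90-fold), both feedback inhibitors of the pathway.

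Camera called 0 of 30 lists between E9 back and tail. The signs of median, mean and test differed for HOXC, whose median log2 was 2.80 and mean -0.98 with 4 genes higher and 2 lower of 7. By edgeR's quasi-likelihood test 6108 of 15330 genes passed, 3413 higher and 2695 lower in back, against 2399 and 946 with limma on the deposited TPM. Without tail replicate 2 the count fell to 2527, and without tail replicate 1 it was 3875. The keratinocyte list summed to 597 and 628 CPM in the tail libraries and to 1789 CPM in anterior dorsal replicate 2, against 53.8 to 148 CPM in the other E9 libraries.

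Between E9 scalp and tail, the ends of the axis, HOXC10 was 2955-fold higher in tail (818 to 24410), HOXC8 77.4-fold (26.2 to 378), HOXC13 339-fold and HOXC12 at least 1384-fold, with 0 counts in scalp. HOXA11 was at least 468-fold and HOXB13 at least 649-fold higher in tail, and HOXA5 135-fold. HOXB13, at 0 counts in scalp, lost its call with the keratinocyte level as a covariate (log2 SE 0.570 before and 20.8 after, direction unchanged). ALX1 (255-fold), GSC (83.8-fold) and SIX2 (5.90-fold) were higher in scalp, whereas ZIC1, a zinc finger factor of dorsal mesoderm and neural tissue, averaged 13.4 ± 1.18 CPM in scalp and 264 ± 15.2 CPM in tail. FGF10, a mesenchymal growth factor, was 4.54-fold higher in tail. Camera called HOXA (10 of 11 lower in scalp, 11 adjusted over the list alone), HOXB (10 of 10 on either adjustment) and HOXC (6 of 7, or 7 adjusted over the list alone), at adjusted p = 1.16e-12, 9.25e-12 and 1.10e-07. These 3 calls held, at adjusted p = 0.00987, 0.00987 and 0.0201 with an estimated correlation.

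Other lists called between E9 scalp and tail were weaker. Feather bud genes were 4 higher and 7 lower of 19 (4 and 11 adjusted over the list alone), with TNC 8.56-fold and SOX18 3.72-fold higher in tail (camera adjusted p = 0.0403, and adjusted p = 0.559 with an estimated correlation). Smooth muscle genes were 2 higher and 6 lower of 10 on either adjustment, with MYOCD 10.1-fold higher in tail and the pericyte receptor gene PDGFRB 4.41-fold higher in scalp (adjusted p = 0.0400, and adjusted p = 0.559 with an estimated correlation). Both of those calls were lost, at adjusted p = 0.0535, in the fit with the replicate number as a block. Of 12 mitochondrial genome transcripts 10 were higher in scalp, or 12 adjusted over the list alone, such as ND4L at 2.25-fold (adjusted p = 4.25e-05, and adjusted p = 0.441 with an estimated correlation). No member of the keratinocyte list passed, on either adjustment, though its camera adjusted p was 0.0167, and adjusted p = 0.766 with an estimated correlation. WNT genes were 7 higher and 14 lower of 38 (7 and 15 adjusted over the list alone), with RSPO1 5.35-fold higher in scalp and DKK3 3.15-fold higher in tail. By edgeR's quasi-likelihood test 4087 of 15330 genes passed, 2434 higher and 1653 lower in scalp (853 and 904 with limma on TPM). The count was 1731 without tail replicate 2 and 2402 without scalp replicate 1, and the genes lower in scalp numbered 813 without tail replicate 1 and 817 without scalp replicate 2.

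Markers of each E9 region, defined as genes past the test of all regions and higher than each other region by a log2 fold of at least 1, numbered 271 in scalp, 63 in neck, 16 in anterior dorsal, 9 in posterior dorsal and 139 in tail skin. Scalp markers included GSC, POU4F1, ALX1 and DBX2. Neck markers included RFX6 (23.9 ± 2.92 CPM), ZIC2 and HOXA2 (104 ± 8.14 CPM). ENPP3 (27.8 ± 3.94 CPM), IRX4 and HOXB8 marked anterior dorsal skin and HOXD10 (10.2 ± 0.225 CPM) posterior dorsal skin. HOXB13 (48.7 ± 4.01 CPM), HOXC12, HOXC13 and SERPINF2 marked tail. In all 7228 genes differed between E9 regions, or 4806 without tail replicate 1 and 3865 without tail replicate 2. Adult markers numbered 424, 57, 62, 53 and 302 in the same order, with 9200 genes differing between regions. They included KRT75, TGM4 and AQP9 in scalp, MYL10 and the somatostatin gene SST (326 ± 82.6 CPM) in neck, PLIN4 (205 ± 5.68 CPM) in anterior dorsal and HOXC12, HOXA11, GAP43 and SALL1 in tail follicles.

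In the adult scalp and back comparison KRT75, an alpha keratin of the feather rachis, averaged 2057 ± 301 CPM in scalp and 0.355 ± 0.351 CPM in back, and the transglutaminase gene TGM4 201 ± 52.2 and 0.328 ± 0.373 CPM. The water channel gene AQP9 was 128-fold and MMP9, a matrix protease gene, 36.0-fold higher in scalp. ALDH1A3, which makes retinoic acid, was 11.1-fold higher. SOSTDC1, a secreted WNT and BMP modulator, was 5.79-fold, the BMP antagonist gene GREM1 6.28-fold, SHH 1.93-fold and ZIC1 9.22-fold higher in back. HOXC4, HOXC6 and HOXC9 were at least 40.6-fold, 30.0-fold and 16.3-fold higher in back, and HOXA5 110-fold. HOXC8 was at least 82.6-fold higher, a call lost without scalp replicate 1 and with the keratinocyte level as a covariate (log2 SE 1.80 before and 2.82 after, direction unchanged). HOXC10 was at least 400-fold higher in back, but its call rested on posterior dorsal follicles and was lost without anterior dorsal replicate 2 or with anterior dorsal alone as back.

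Dermal fibroblast genes were lower in adult scalp for 14 of 15 and higher for 1, on either adjustment, with FBN1 4.31-fold, COL3A1 2.85-fold and LUM 3.58-fold higher in back (camera adjusted p = 6.79e-06, and adjusted p = 0.0564 with an estimated correlation); TWIST2 turned its direction with the deposited TPM. HOXA had 8 lower and 1 higher of 10, HOXB 7 lower of 8 and HOXC 6 lower of 7, the same adjusted over the list alone, at adjusted p = 6.93e-06, 2.83e-06 and 0.000350. With an estimated correlation these were adjusted p = 0.0527, 0.0527 and 0.0641. Of 11 leukocyte genes 9 were lower and 1, CD3E, which turned with TPM, higher (adjusted p = 0.00978, and adjusted p = 0.489 with an estimated correlation). Of 18 proliferation genes 9 were lower, such as MCM2 at 1.89-fold (adjusted p = 0.00144, and adjusted p = 0.489 with an estimated correlation), and of 17 immediate early and stress genes 9 were lower and 1, FOSL2, which turned with TPM, higher (10 and 1 adjusted over the list alone), with the chaperone genes HSPH1 7.71-fold and HSP90AA1 4.38-fold higher in back (adjusted p = 0.00236, and adjusted p = 0.489 with an estimated correlation). Melanocyte genes were higher in scalp for 5 of 7 and lower for 1, on either adjustment, with KIT 2.88-fold (adjusted p = 0.0457, and adjusted p = 0.312 with an estimated correlation); the log2 fold of MITF was 0.63 with TMM and -0.19 with TPM.

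Mitochondrial transcripts were higher in adult scalp for 8 of 12 (10 adjusted over the list alone), with adjusted p = 0.000370, and adjusted p = 0.489 with an estimated correlation, but 4 of those 8 turned with the deposited TPM. Keratinocyte genes were 6 higher and 2 lower of 13, of which 5 turned with TPM, and adipocyte genes 5 higher and 1 lower of 8, of which PPARG and SCD turned; neither list was called, and counts adjusted over the list alone were the same. Trunk and limb factors were 2 higher and 11 lower of 18 (3 and 11 adjusted over the list alone). By edgeR's quasi-likelihood test 6394 of 14593 genes passed between adult scalp and back, 3296 higher and 3098 lower, but limma on the deposited TPM gave 508 higher and 10807 lower, with the median gene at -0.60 log2. Of the 6394 genes called, 2220 changed sign with TPM. With TMM the median gene lay at -0.0043 log2, so the TPM folds were shifted as a body. Such a shift can turn smaller positive folds without a change particular to the gene. The 10 most abundant genes took 15.0% and 15.7% of counts in the scalp libraries and 8.0% to 11.5% in the other adult libraries.

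Between adult back and tail follicles, smooth muscle genes stood out. All 10 of 10 were lower in back, MYH11 3.52-fold and ACTA2 2.63-fold, on either adjustment (camera adjusted p = 5.42e-06, and adjusted p = 0.448 with an estimated correlation), and the list summed to 2248 and 1942 CPM in tail against 517 to 982 CPM in the other adult libraries. GAP43, a growth-associated gene of axons, was 58.0-fold, HOXA11 722-fold, HOXC13 64.4-fold and HOXC12 at least 720-fold higher in tail. With posterior dorsal alone as back the log2 folds of HOXA11 and HOXC13 were -6.93 and -4.91 in place of -9.50 and -6.01. HOXC4 was 38.4-fold higher in back. BMP pathway genes were 13 higher and 9 lower of 28 (13 and 10 adjusted over the list alone): BAMBI was 7.21-fold, BMP2 5.53-fold and BMP5 8.51-fold higher in back and GREM1 4.28-fold higher in tail. HOXC10 had a log2 fold of -3.88 with back as the mean of both dorsal regions and 0.79 with posterior dorsal alone, so its direction rested on the anterior dorsal libraries. HOXC6 was 2.73-fold higher in back, a call lost without tail replicate 2. It was also lost with the keratinocyte level as a covariate, where the log2 fold went from 1.45 to -0.16 (SE 1.27).

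Keratinocyte genes were higher in adult back than tail for 6 of 13 (7 adjusted over the list alone), EPCAM 1.76-fold (adjusted p = 0.0223, and adjusted p = 0.448 with an estimated correlation), and melanocyte genes for 3 of 7 (5 adjusted over the list alone), with the same p-values. Erythroid genes were lower in back for 5 of 6 on either adjustment (adjusted p = 0.0223, and adjusted p = 0.533 with an estimated correlation); the list summed to 238 and 1022 CPM in the tail libraries and 29.1 to 113 CPM in the others. Interferon genes were 1 higher and 7 lower of 17, or 1 and 8 adjusted over the list alone (adjusted p = 0.0223, and adjusted p = 0.448 with an estimated correlation), and proliferation genes 0 and 6 of 18, or 1 and 9 adjusted over the list alone (adjusted p = 0.0364, and adjusted p = 0.633 with an estimated correlation). Neural and Schwann genes were 2 higher and 5 lower of 10 on either adjustment. By edgeR's quasi-likelihood test 4717 of 14593 genes passed, 2319 higher and 2398 lower in back (1029 and 3221 with limma on TPM, median -0.14 log2). The count was 2872 without tail replicate 2, 3082 without tail replicate 1 and 607 with the keratinocyte level as a covariate. That covariate raised the median standard error across genes 2.84-fold and ended the calls of HOXA11 (log2 fold -9.50 with SE 0.330 before, -6.92 with SE 2.93 after), HOXC4 (5.26 with SE 0.546, then 5.42 with SE 1.60), HOXC13 (-6.01 with SE 0.326, then -4.05 with SE 2.21) and ACTA2 (-1.40 with SE 0.122, then -0.57 with SE 0.269). It also ended that of HOXC12, whose counts outside tail were 0 (log2 SE 0.387 before and 14.1 after, direction unchanged).

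Between adult scalp and tail follicles, feather and skin differentiation genes were higher in scalp for 5 of 5 on either adjustment (camera adjusted p = 0.00285, and adjusted p = 0.151 with an estimated correlation). F-KER, a feather keratin of a multigene family whose reads near-identical copies may share, averaged 23850 ± 1893 CPM in scalp and 1.72 ± 0.219 CPM in tail, and KRT75 2057 ± 301 and 0.798 ± 0.229 CPM. BMP2 and its inhibitor gene BAMBI were 7.36-fold and 10.5-fold and MSX2, a homeobox target of BMP signals, 6.46-fold higher in scalp. GREM1 was 26.9-fold, SOSTDC1 7.34-fold, WNT2B 8.59-fold and RSPO2 10.4-fold higher in tail. All 7 of 7 melanocyte genes were higher in scalp, KIT 5.65-fold (adjusted p = 0.00165, and adjusted p = 0.0914 with an estimated correlation); ERBB3, a gene of the neural and Schwann list, turned with TPM. ZIC1 was 46.4-fold and HOXA5 99.0-fold higher in tail, HOXC10, HOXC12 and HOXC13 at least 439-fold, 287-fold and 202-fold, and HOXD3 5.31-fold higher in scalp.

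**Figure D3:**
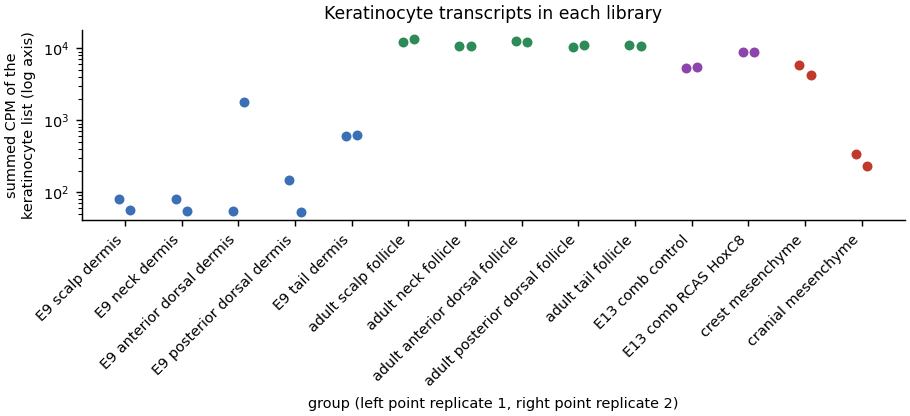
Summed CPM of the keratinocyte gene list in each library, on a log axis, with the 14 groups on the horizontal axis and one point per library. E9 dermis lies at 53.8 to 148 CPM except for anterior dorsal replicate 2 (1789) and tail (597 and 628), and the crest libraries (5820 and 4257) lie above the cranial feather ones (337 and 231).

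Connective tissue and cycling genes were lower in adult scalp than tail. Dermal fibroblast genes were lower for 13 of 15 (LUM 4.32-fold), smooth muscle genes for 10 of 10, proliferation genes for 14 of 18 (MCM2 2.44-fold) and hedgehog genes for 7 of 11, with none higher, at camera adjusted p = 9.95e-05, 9.95e-05, 0.000646 and 0.0310. These were adjusted p = 0.0771, 0.309, 0.379 and 0.309 with an estimated correlation. Immediate early and stress genes were 2 higher and 11 lower of 17, with HSPH1 6.87-fold higher in tail, leukocyte genes 1 and 9 of 11 and erythroid genes 0 and 5 of 6, at adjusted p = 0.00942, 0.0165 and 0.0189, and each at adjusted p = 0.379 with an estimated correlation. Interferon genes were lower for 11 of 17, or 13 adjusted over the list alone (adjusted p = 0.00251), trunk and limb factors 4 higher and 13 lower of 18 (adjusted p = 0.0258), and mitochondrial transcripts higher for 9 of 12, or 10 adjusted over the list alone (adjusted p = 0.000883), each at adjusted p = 0.309 with an estimated correlation; MT-CO1, ATP6 and ND4L turned with TPM, as did NR2F1 of the trunk and limb factors and TXNIP of the stress genes. Keratinocyte genes were 8 higher and 3 lower of 13, but CDH1, KRT14 and DSG2 turned with TPM (adjusted p = 0.0325, and adjusted p = 0.327 with an estimated correlation).

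The HOX lists were lower in adult scalp than tail for 10 of 10 HOXA, 8 of 8 HOXB and 6 of 7 HOXC genes (camera adjusted p = 1.11e-06, 8.31e-05 and 0.000122, and adjusted p = 0.0670, 0.0710 and 0.0710 with an estimated correlation). The HOXC median log2 was -7.91, or -4.00 with genes at 0 counts set to their bound. Except where given, counts adjusted over the list alone were the same. By edgeR's quasi-likelihood test 7917 of 14593 genes passed, 3925 higher and 3992 lower in scalp, against 777 and 10999 with limma on TPM (median -0.74 log2), and 2474 of them changed sign with TPM. With the keratinocyte level as a covariate 1619 passed and the median standard error rose 3.43-fold. The calls of F-KER (log2 fold 13.75 with SE 1.17 before, 12.07 with SE 2.83 after), HOXC13 (-11.55 with SE 0.762, then -8.78 with SE 3.49), KIT (5.65-fold with a log2 SE of 0.184, then a log2 fold of 1.96 with SE 0.650) and LUM (-2.11 with SE 0.163, then -0.77 with SE 0.389) ended. The call of HOXC12, at 0 counts in scalp, also ended (log2 SE 0.544 before and 19.2 after, direction unchanged).

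To ask whether the scalp and tail contrast differed between stages, both tables were fitted together with an interaction term, which also holds any difference between the kits and tissues of the 2 tables. It called 7086 of 15355 genes, 3590 with a more positive contrast at E9 and 3496 with a more negative one by edgeR's quasi-likelihood test, but 8265 and 916 with limma on TPM, where the median was 0.62 log2. VIM, an intermediate filament gene of mesenchyme, had a log2 fold of 1.48 at E9 and -2.75 in adults. HOXB3 had log2 folds of -6.74 and -2.46 and HOXD8 of 0.86 and -1.98 at the 2 stages. No HOXC gene passed, but their log2 standard errors ran from 1.63 (HOXC6) to 2356 (HOXC4), as adult scalp lacked HOXC counts. The test could therefore not tell whether the HOXC contrasts differed between stages. Of genes called at both stages 1024 had the same direction, where independent lists give 1025, and 1246 the opposite one, where they give 1039. The largest group, 841 genes, was higher in scalp at E9 and in tail in adults (646 by chance, one-sided Fisher's exact p = 2.15e-22), an overlap that was not run under the alternatives. All Fisher tests here count genes as independent units, which they are not, so their p-values do not measure the spread between samples. Genes higher in tail at both stages numbered 539 (418 by chance, one-sided Fisher's exact p = 3.29e-13), and genes higher in scalp at both 485 (607 by chance, p = 1). With limma on the deposited TPM the tail overlap was 566 (611 by chance, one-sided Fisher's exact p = 1), and with a log2 fold of at least 1 the scalp overlap was 105 (86.4 by chance, p = 0.0189). The shared count was 500 without E9 tail replicate 2 and 652 without E9 scalp replicate 1. Across genes, which are not independent replicates, the log2 folds had a Pearson r of 0.0278 and a Spearman rho of -0.0751.

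The retrovirus experiment asked which genes respond to HoxC8 in E13 comb skin. HOXC8 itself, the check of the labels, had 0 counts in both controls and 3179 and 1336 counts in the HoxC8 combs, 255 ± 176 CPM, which is at least 1216-fold higher (adjusted p = 0.00646 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, higher in 2 of 2 libraries). MSX2 rose 189-fold, from 1.13 ± 0.110 to 216 ± 8.15 CPM, and SHH, the ligand of the hedgehog pathway, 73.9-fold, from 0.931 ± 0.201 to 69.8 ± 4.80 CPM. TCF7, a transcription factor of WNT signalling, rose 388-fold (counting interval 133 to 1885) and EDQM3, of the epidermal differentiation complex whose related genes may share reads, 473-fold (162 to 2295). The bud gene PRDM1 rose 7.03-fold, DLX5 3.77-fold and the pigment gene TYRP1 8.86-fold. ALX1 fell 3.94-fold, FGF10 2.77-fold, and the dermal matrix genes DPT 5.95-fold, LUM 3.22-fold and POSTN 2.70-fold. FGF10 lies on chromosome Z, whose genes had a median log2 fold of -0.71 in this comparison. Of the other HOXC genes only HOXC13 had enough counts for a test, and at 1.75 ± 0.283 CPM in HoxC8 combs and 3.44 ± 1.27 CPM in controls it did not pass (adjusted p = 0.184).

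Hedgehog genes rose for 8 of 11 and none fell (9 adjusted over the list alone), with GLI1 4.99-fold (camera adjusted p = 0.00311, and adjusted p = 0.615 with an estimated correlation). The HoxC8 fit left 2 residual degrees of freedom, so camera with an estimated correlation had little power for these lists. Notch genes rose for 7 of 16, such as HEYL at 5.73-fold and NOTCH1 at 4.76-fold (adjusted p = 0.00967, and adjusted p = 0.615 with an estimated correlation). Keratinocyte genes rose for 9 of 13, with CDH1 4.78-fold and TP63 3.58-fold (adjusted p = 0.00256, and adjusted p = 0.615 with an estimated correlation), while KRT14 and KRT17, chosen after their values were seen, had log2 folds of 0.15 and -0.06; the list summed to 8779 and 8750 CPM in HoxC8 combs and 5250 and 5540 CPM in controls. Smooth muscle genes rose for 7 of 10 and fell for 1, MYH11 7.97-fold and MYOCD 17.3-fold (adjusted p = 0.00542, and adjusted p = 0.615 with an estimated correlation). Immediate early and stress genes rose for 11 of 16, or 12 adjusted over the list alone, EGR1 8.24-fold (adjusted p = 0.00256, and adjusted p = 0.615 with an estimated correlation). Proliferation genes rose for 10 of 18 and fell for 1, TOP2A 2.06-fold (adjusted p = 0.0496, and adjusted p = 0.615 with an estimated correlation; adjusted p = 0.0611 with the replicate block).

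Dermal fibroblast genes fell for 8 of 15 and rose for 2 (adjusted p = 0.0417, and adjusted p = 0.750 with an estimated correlation). Leukocyte genes fell for 5 of 11, PTPRC 3.02-fold and CD74 2.13-fold, without a camera call (adjusted p = 0.0504), and their list summed to 372 and 408 CPM in HoxC8 combs and 736 and 605 CPM in controls. Counts adjusted over the list alone were the same as over all genes for the Notch, keratinocyte, smooth muscle, proliferation, fibroblast and leukocyte lists. WNT genes rose for 13 and fell for 4 of 41 (14 and 4 adjusted over the list alone), with WNT16 9.79-fold and WIF1 7.21-fold, and feather bud genes rose for 6 and fell for 3 of 19 (8 and 4 adjusted over the list alone). Skeletal muscle genes rose for 3 of 5 on either adjustment, and melanocyte genes rose for 5 and fell for 1 of 11 (7 and 1 adjusted over the list alone). By edgeR's quasi-likelihood test 4641 of 13193 genes passed, 2572 higher and 2069 lower (2355 and 1116 with limma on TPM). The count was 1762 without HoxC8 replicate 1 and 2151 without HoxC8 replicate 2, and 3340 genes were lower without control replicate 2. The call of HOXC8 was lost with no filter on low counts and without either control library.

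The groups of the HoxC8 experiment also differed in W chromosome transcripts, at 15.1 CPM without TMM factors in each control and 2236 and 2227 in the HoxC8 combs. Of 35 W genes tested 34 rose, and of 583 Z genes 36 rose and 306 fell, with a median log2 fold of -0.71. HINTW, a W-linked gene of females, had 0 and 1 counts in controls and 7440 and 9029 in HoxC8 combs. Outside Z and W 2502 genes rose and 1763 fell of 12575, mitochondrial genes included.

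**Figure D4:**
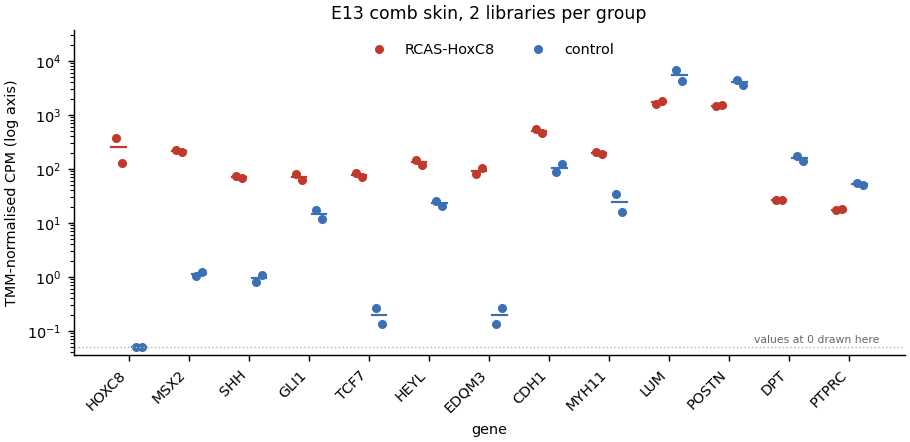
TMM-normalised CPM of 13 genes in E13 comb skin on a log axis, with genes on the horizontal axis, one point per library and a line at the mean of each group. SHH averaged 69.8 CPM in the HoxC8 combs and 0.931 CPM in controls, and values at 0, such as HOXC8 in controls, are drawn at the dotted line.

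The last comparison asked how HOXC genes differ between the long crest feathers and the neighbouring short cranial feathers of Polish chickens. HOXC10 averaged 33.2 ± 10.8 CPM in crest (905 and 1293 counts) and 0.588 ± 0.0166 CPM in cranial feather mesenchyme (30 and 21 counts), a 56.1-fold difference, but it missed the threshold (adjusted p = 0.149 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, higher in 2 of 2 libraries). HOXC9 had 96 and 134 counts in crest and 0 in both cranial libraries, at least 98.9-fold, and HOXC8 averaged 1.03 ± 0.290 against 0.106 ± 0.122 CPM. HOXC12 had 3 and 3 counts in crest and 0 in both cranial libraries, too few for a fold. HOXB3 averaged 0.280 ± 0.0838 CPM in crest and 4.24 ± 1.53 CPM in cranial mesenchyme. KRT5, a keratin of basal epidermis, averaged 2206 ± 585 and 126 ± 0.886 CPM, and TP63, a regulator of stratified epithelium, 216 ± 56.9 and 8.82 ± 0.797 CPM. WNT6 (52.7-fold), ALX1 (99.6-fold) and MSX2 (26.1-fold) had higher means in crest, and MYH11 (17.2-fold), FGF10 (54.9-fold) and CSF1R (3.84-fold) in cranial mesenchyme.

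No gene passed over all 14714 genes in the crest comparison: edgeR's quasi-likelihood test called 0, with 1914 genes at an unadjusted p under 0.05, limma on the deposited TPM called 0 and DESeq2 769. The biological coefficient of variation was 0.516, and the cranial feather libraries correlated with each other at 0.883 across genes, against at least 0.961 for the other pairs. Without cranial replicate 1 the count was 8538, without cranial replicate 2 it was 3142, without crest replicate 1 it was 25 and without crest replicate 2 it was 34; with the replicate number as a block it was 427. Over those 5 fits and DESeq2 the log2 fold of HOXC10 ranged from 5.45 to 6.12. HOXC10 passed with DESeq2 (log2 fold 5.82, DESeq2 adjusted p = 3.78e-18) and with the replicate block. A fit without 1 library leaves a lone library in a group and takes the spread from the other pair alone. Calls in such fits therefore say little about a gene.

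Camera called 18 of 30 lists between crest and cranial mesenchyme, none of which held with an estimated correlation. The crest fit left 2 residual degrees of freedom, so that version had little power and a lost call says little about a list. Adjusted over the list alone, 11 of 12 keratinocyte genes were higher in crest (camera adjusted p = 1.13e-11, and adjusted p = 0.318 with an estimated correlation), and the list summed to 5820 and 4257 CPM in crest and 337 and 231 CPM in cranial libraries. Likewise adjusted over the list alone, 16 of 38 WNT genes (adjusted p = 1.27e-12), 3 of 3 HOXC genes (adjusted p = 7.61e-05), 4 of 17 trunk and limb factors (adjusted p = 1.06e-05) and 3 of 11 hedgehog genes (adjusted p = 0.00292) were higher in crest and none lower, each at adjusted p = 0.318 with an estimated correlation. Cranial mesenchyme factors were higher for 4 of 17 (adjusted p = 1.06e-05, and adjusted p = 0.371 with an estimated correlation), and feather bud genes for 8, with 2 lower, of 19 (adjusted p = 0.0114, and adjusted p = 0.318 with an estimated correlation). Lower in crest, adjusted over the list alone, were 7 of 10 smooth muscle genes (adjusted p = 1.34e-06, and adjusted p = 0.318 with an estimated correlation) and 10 of 11 leukocyte genes (adjusted p = 7.60e-07, and adjusted p = 0.351 with an estimated correlation), such as CD3E, of T cells, with 103 ± 1.64 and 367 ± 63.2 CPM. Those lists summed to 1885 and 1854 CPM (smooth muscle) and 6518 and 5627 CPM (leukocyte) in crest against 11510 and 16250, and 14260 and 21810 CPM, in cranial libraries.

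Camera also called erythroid genes (3 of 9 lower in crest, adjusted p = 0.00585, and adjusted p = 0.318 with an estimated correlation), skeletal muscle genes (2 of 7 lower, adjusted p = 0.00548, and adjusted p = 0.347 with an estimated correlation) and HOXB genes (1 of 5 lower, adjusted p = 0.0144, and adjusted p = 0.455 with an estimated correlation), all adjusted over the list alone. Neural and Schwann genes were higher for 1 of 11 (adjusted p = 0.00995, and adjusted p = 0.455 with an estimated correlation), and BMP genes for 2, with 1 lower, of 27 (adjusted p = 0.0144, and adjusted p = 0.318 with an estimated correlation). The interferon, proliferation, matrix and Notch lists had no member past the test even adjusted over the list alone, at camera adjusted p = 0.00501, 0.0122, 0.0240 and 0.0415. These were adjusted p = 0.455, 0.541, 0.342 and 0.466 with an estimated correlation. The replicate block ended the calls of the BMP (adjusted p = 0.0698), matrix and proliferation lists. Over all comparisons camera made 72 calls among 240 list tests, of which 5 held with an estimated correlation: HOXA and HOXB in E9 scalp and back, and HOXA, HOXB and HOXC in E9 scalp and tail. The HoxC8 and crest calls had little power to hold, at 2 residual degrees of freedom. Median, mean and test differed in sign in 31 of the 240, none of them called.

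**Figure D5:**
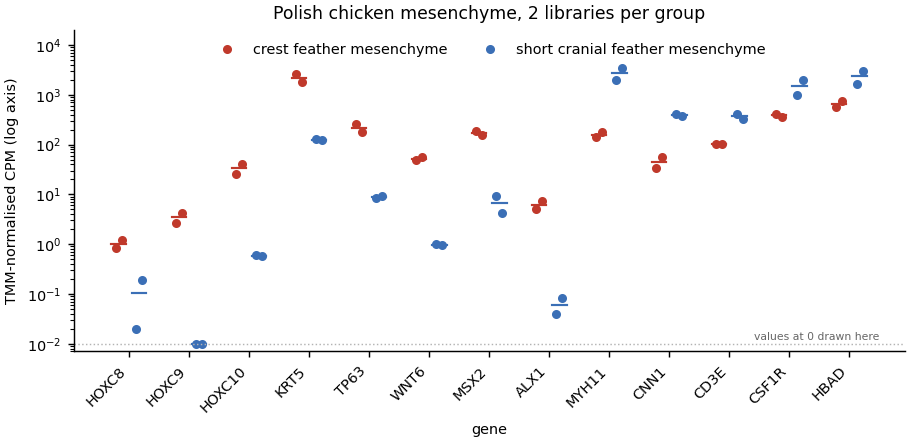
TMM-normalised CPM of 13 genes in crest and short cranial feather mesenchyme on a log axis, with genes on the horizontal axis, one point per library and a line at the mean of each group. HOXC10 averaged 33.2 CPM in crest and 0.588 CPM in cranial libraries, and values at 0, such as HOXC9 in cranial libraries, are drawn at the dotted line.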

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

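The prediction on sex and autosomal genes was written before its result was seen, and all other tests of explanations in this part were chosen only after the result they measure was seen. The single genes below stood out because their scalp and tail contrast differed between E9 dermis and adult follicles by the interaction test; no group was large enough for a test of single samples that lie apart.

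Comb skin injected with the HoxC8 virus had 2236 and 2227 CPM from chromosome W against 15.1 in each control, so sex and treatment went together in these libraries. The Z genes had a median log2 fold of -0.71 in the HoxC8 comparison. In E9 dermis their slope on the log2 W level, beside terms for region, was scaled to the full range of that level. Its median over 575 Z genes was -0.58, which fits a difference in sex for that chromosome. Autosomal genes here are all genes outside Z and W, mitochondrial genes included. Over 4191 called autosomal genes the same E9 estimate, taken in the direction of the HoxC8 call, had a median of 0.0315 (bootstrap interval 0.0256 to 0.0376). Their median absolute log2 fold was 0.89. The bootstrap drew genes as if independent and leaves out the spread between embryos. As estimated from these few E9 libraries, the sex difference accounts for little of the autosomal change. That estimate mixes sex with epidermal content in anterior dorsal dermis, however. There the library with the lower W level (64.0 against 2355 CPM, without TMM factors) held more keratinocyte transcripts. A larger part for sex is therefore not excluded. A larger share of epidermal RNA would lower other cell types alike, but smooth muscle genes had a median log2 fold of 2.35 (quartiles 0.38 and 3.01, 10 genes) and dermal fibroblast genes one of -0.64, which argues against it for smooth muscle genes. Of the 2502 autosomal genes that rose 25.9% exceeded the median log2 fold of the keratinocyte list, 0.97, by over 2 standard errors, and 78.4% exceeded the log2 ratio of 3 summed keratins, 0.31, so for the other genes that share cannot be told apart from changes within cells, and sex differences particular to comb skin, the virus itself and HoxC8 also stay open.

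HOXC10 had a log2 fold of 5.81 between crest and short cranial feather mesenchyme (edgeR adjusted p = 0.149, not passing, n = 2 per group), while keratinocyte transcripts were higher in crest too. Its log2 fold stayed at 4.33 or more over 8 other scalings, filters and tools, the deposited TPM included. The median gene lay at 0.0186 log2 with TMM and with DESeq2's size factors, and at 0.0573 with TPM. Scalings that differ so little could not remove a fold of that size, so their agreement decides little. A scaling factor moves all genes of a library alike, however, and leaves the distance of HOXC10 from the median gene unchanged. That distance, 5.81 against 0.0186 with TMM, argues against scaling as the source of the difference from the median gene. HOXC10 exceeded the median of the keratinocyte list (4.11, interquartile range 3.16 to 4.51, 12 genes) by 1.71 on the log2 scale, more than 2 of its standard errors (0.602) but less than those plus the interquartile range, so epidermal cells that carry HOXC10 and mesenchyme that expresses it cannot be told apart. The biological difference named by the design, long against short feathers, also stays open.

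Replicate 2 of E9 anterior dorsal dermis had less HOXC10 (53.5 CPM against 154 CPM) and HOXA10 than replicate 1, and it also held 1789 CPM of keratinocyte transcripts against 54.7 CPM. Dilution by epidermal RNA would lower all HOX genes alike, but the median log2 ratio of 6 genes of paralog groups 9 to 13 lay at -1.17 and that of 16 genes of groups 1 to 8 at 0.01, a difference of -1.18. A more anterior level of dissection may contribute: 100 percent of groups 9 to 13 and 50 percent of groups 1 to 8 were lower in replicate 2. With a single library this cannot be told apart from other differences between the embryos, and no biological explanation was tested.

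Among HOX genes the E9 minus adult difference of the scalp and tail log2 contrast was -4.06 for HOXA2 (-5.23 at E9, -1.21 in adults), -2.99 for HOXA7 (-6.61 and -3.65), -4.32 for HOXB3 (-6.74 and -2.46) and -2.21 for HOXB2 (-4.57 and -2.41), all of them less negative in adult follicles. The difference was -2.35 for HOXB4 (-6.16 and -3.84), whose call was lost with the deposited TPM (-0.02) and without E9 scalp replicate 1, E9 scalp replicate 2 or adult scalp replicate 1. HOXB7 differed by 2.29 (-1.92 at E9 and -4.25 in adults) and HOXD8 by 2.79 (0.86 and -1.98), and HOXD3 by -2.96, with a contrast of 2.41 in adults and one of -0.51 at E9 that did not pass. HOXB8 differed by 6.54, but it had 0 counts in both adult scalp libraries, so its adult contrast is known only as at least 11.1-fold. HOXB1 (-4.50) had too few counts in adult follicles for a test of the adult contrast alone.

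Of the 8 other genes with the smallest p in that test VIM differed by 4.18 (1.48 at E9 and -2.75 in adults), FHOD3, a formin of muscle sarcomeres, by 4.24 (2.56 and -1.73), SVIL, an actin-binding protein gene, by 2.71 (0.62 and -2.13) and the matrix glycoprotein gene THBS1 by 3.88 (1.57 and -2.36). PDE5A, a cGMP phosphodiesterase gene, differed by 4.97 (2.63 and -2.40), AKR1D1, a steroid reductase gene, by 5.49 (-1.53 in adults), CUBN by 5.17 (0.71 and -4.50) and CMTM7 by -5.57 (5.40 in adults, with -0.13 at E9, which did not pass).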

How the results depend on the processing

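The covariates for keratinocyte and W chromosome levels were chosen after the data were seen, and the other alternatives of this part were planned. Of 5352 values under the alternatives for 267 pairs of a named gene and a comparison, 5128 kept their direction and side of the threshold, 130 lost their call, 90 gained one (all in the crest comparison) and 4 reversed. Scaling with DESeq2's size factors, leaving out Z and W genes and the stricter filter ended no call of a named gene, and the W covariate, run on the E9 table alone, ended none there. Where a cause is not given in this part, the cause was not tested.

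With an added log2 fold of at least 1, which removes smaller changes by construction, the counts were 1643 (E9 scalp and back), 1941 (E9 back and tail), 1949 (E9 scalp and tail), 3714 (E9 any region), 2051, 1522 and 3678 in the adult comparisons in the same order, 4674 (adult any region), 2055 (HoxC8), 4227 (interaction) and 377 (shared by both stages, above the number by chance). Limma on the deposited TPM gave 2556, 3345, 1757 and 3836 at E9, 11315 in adult scalp and back and 596 shared (642 by chance); the log2 folds of MITF and MSX2 in adult scalp and back reversed to -0.19 and -0.14. With the keratinocyte covariate adult back and tail gave 607, adult scalp and tail 1619 and adult markers 565, and HOXC6 in adult back and tail reversed to -0.16 (SE 1.27). With posterior dorsal alone as back HOXC10 in adult back and tail reversed to 0.79. Of 72 camera calls 5 held with an estimated correlation, a version with little power at the 2 residual degrees of freedom of the HoxC8 and crest fits. In the crest comparison DESeq2 called 769 genes.

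With the replicate number as a block the crest comparison gave 427 genes. Deviations of same-numbered libraries correlated at -0.559 to 0.583 between E9 groups, -0.118 to 0.111 between adult groups, -0.052 in the comb and -0.0734 in the crest table. The medians of -0.0711 at E9 and -0.00877 in adults show no pairing common to all regions. The comb and crest values rest on 1 pair each, so they cannot exclude that same-numbered libraries belong together. The block also ended the calls of the E9 scalp and back genes HOXC12 and TP63 and of 6 lists: feather bud and smooth muscle (E9 scalp and tail), proliferation (HoxC8), and BMP, matrix and proliferation (crest). It added calls for 6 lists, the trunk and limb factors (adult scalp and back), skeletal muscle, melanocyte and leukocyte genes (HoxC8) and adipocyte and retinoic acid genes (crest), and for 15 named crest genes. It changed no other call of a named gene or list.

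Leaving out one library at a time, where a lone library is assumed to vary like the others, gave 2424 to 5223 genes in E9 scalp and back, 2527 to 6390 in E9 back and tail, 1731 to 4647 in E9 scalp and tail, 3865 to 8004 over all E9 regions, 2872 to 5270 in adult back and tail, 1762 to 6902 in the HoxC8 comparison, 25 to 8538 in the crest comparison and 500 to 1134 shared by both stages. It left the counts of adult scalp and back (5293 to 6278), adult scalp and tail (6425 to 8057), all adult regions (8014 to 9138), E9 markers (361 to 690), adult markers (811 at the least) and the interaction (5837 to 7375) within 1.5 times. Depth limits HOX genes near the floor: with 3 counts over a group, folds against scalp are bounds or have wide intervals, and the comb libraries are the shallowest.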

Other observations

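The tests in this part were planned, while the lists described were picked after their values were seen. In the HoxC8 combs, of 9 neural and Schwann genes 3 rose (5 adjusted over the list alone) and none fell: TUBB3, a neuronal tubulin gene, averaged 245 ± 2.37 CPM in HoxC8 combs and 22.3 ± 3.60 CPM in controls (SD, n = 2), ERBB3 113 ± 15.4 and 35.8 ± 8.86 CPM, and GAP43 11.6 ± 0.737 and 1.33 ± 0.206 CPM. Of 12 cartilage and bone genes 5 rose on either adjustment, RUNX2, a transcription factor gene of bone, 3.62-fold and ALPL, its alkaline phosphatase, 2.85-fold. BMP pathway genes rose for 10 and fell for 4 of 29 (11 and 4 adjusted over the list alone), with BAMBI 4.95-fold and BMP7 3.63-fold, and FGF genes rose for 5 and fell for 5 of 23 on either adjustment, with the receptor gene FGFR3 3.81-fold and ETV4, a target of FGF signals, 7.72-fold. Endothelial genes fell for 4 of 9 and rose for 1 on either adjustment, with VWF 2.45-fold and CDH5 2.15-fold lower. Camera called none of these 5 lists.

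In the Polish mesenchyme, where no gene passed over all genes, adipocyte markers had higher means in the cranial libraries: FABP4 averaged 143 ± 106 CPM against 2.38 ± 1.23 CPM in crest, and ADIPOQ 1746 ± 650 against 618 ± 16.1 CPM. Adjusted over the list alone 1 of 9 adipocyte genes was lower in crest. Genes of the retinoic acid pathway were higher in crest for 3 of 15 when adjusted over the list alone, among them CRABP-I, a retinoic acid binding protein gene (30.7 ± 5.47 against 0.447 ± 0.377 CPM), and ALDH1A3 (50.4 ± 10.9 against 5.93 ± 1.63 CPM). The mean of the neurofilament gene NEFM was 90.8-fold higher in crest, though it did not pass, and COL2A1, a collagen gene of cartilage, averaged 55.5 ± 9.82 and 4.18 ± 2.96 CPM. The mean of NOG, a BMP antagonist gene, was 18.1-fold higher in cranial mesenchyme.

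Several libraries stood apart within their group. Replicate 1 of E9 neck dermis held 695 CPM of skeletal muscle transcripts against 19.9 CPM in replicate 2. CPM from chromosome W at E9 were 44.9 and 2426 in scalp, 74.6 and 67.1 in neck, 2355 and 64.0 in anterior dorsal, 63.6 and 2376 in posterior dorsal and 323 and 53.6 in tail, so most regions mix high and low values, and tail replicate 1 lay between them. Mitochondrial transcripts summed to 29320 and 79840 CPM in the cranial feather libraries.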
